A study of Drosophila melanogaster with 2 samples.

How the data were processed

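ChIP-seq peak lists of CG12299 tagged with GFP were analysed for 2 biological replicates of whole embryos aged 0 to 24 h. Per the labels, the antibody recognised GFP, chromatin was sheared by sonication and the size range was 200 to 800 bp; the antibody field of the labels names CG12299, the tagged protein. Per the labels the genome build was dm6. The aligner, the peak caller and their versions are not given in the sources used here.

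The authors deposited 4 peak lists in narrowPeak format. Per the deposited manifests, a list was called on each replicate's alignment and a further one on both replicates together, each against 1 control alignment, and the thresholded list holds the peaks that passed the authors' irreproducible discovery rate threshold, derived from both replicate lists and the pooled list. The control was not analysed here. The signal column, signalValue, is the authors' peak score, and its scale is not given and is specific to each list. The authors' -log10 q-value column is tied at its top value and was used only to describe the lists and as an alternative ranking. The p-value column holds -1 throughout. The 3 lists without a threshold each hold 30000 peaks, a ceiling of their length. The pooled and replicate 2 lists each held 1 repeated position, which was counted once.

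No read counts were used, so depth and its effect on precision are unknown, and intervals on shares of peaks (95%, exact binomial) cover counting error only. A narrower or shifted summit, as the caller places it, moves the sequence and annotation windows that start from it. The reference was the release 6 assembly of Drosophila melanogaster, whose arm lengths contain all peak ends, with the Ensembl release 115 annotation, from which transposable elements were left out. It held 18277 genes and 24111 TSSs.

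Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. The groups, tests, gene lists, sequence words and the rule for named genes were fixed before the data were examined, as were most alternatives; the rest were added after values had been seen. Replicate overlap compared the 3672 strongest peaks of each replicate, with a minimum overlap of 1 bp, against 1000 random placements. Each summit was assigned to the first fitting class of within 500 bp of a TSS, 5' UTR, CDS, 3' UTR, other exon, intron and intergenic. Thresholded peaks were compared with the 25545 pooled peaks that overlap none of them, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This background holds other peaks of the pooled list, all with a lower signalValue than any thresholded peak. The lowest -log10 q-value was 0.276 in the pooled list and 3.01 in the thresholded list. The comparison thus sets strong peaks against weaker ones, some of them with little statistical backing of their own. P-values across peaks or genes treat these as units, and there are 2 biological replicates.

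For gene lists, genes with a thresholded summit within 1000 bp of a TSS (3414) were counted among genes with a pooled summit in that range (10813), over 20 lists. Sequence words (15) and 7-mers (8192, each merged with its reverse complement) were searched on both strands within 50 bp of the summit. 7-mers were found on 2L and 2R and the called ones tested on 3L, 3R and X. Signal at promoters was compared with 100000 resamples. Named genes are those with the TSS nearest to the 20 peaks of highest signalValue, with a second gene where TSSs tie within 50 bp, CG12299, and up to 4 members per list with the strongest peaks; of 7-mers, the 5 with the smallest p. One gene that this rule names is not reported here.

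The tests were tested on simulated data. With 20 7-mers planted in 5% of simulated peaks, 20 were recovered on the test arms, and a random split of the remaining peaks gave 0. With thresholded genes drawn at random, 0 of 20 gene lists were called, and with 30% of members added to the 4 lists of 50 or more genes, 4 were called. Matched backgrounds were drawn from remaining peaks in GC bins of 2% and the same TSS class, leaving 3640 peaks per side. The GC content matched was that within 50 bp of the summit, the main window for words and 7-mers. Alternatives covered windows, backgrounds, a stricter threshold, other overlap rules and each replicate alone. Backgrounds matched on GC content alone or drawn at random to the matched size, windows of 150 bp, matching at 100 bp, placements from replicate 2's own list and divergent promoters were chosen after seeing the data.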

Results

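Binding of the CG12299 protein was profiled by ChIP-seq in whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying. The flies carried a transgene that makes CG12299 with green fluorescent protein (GFP) at its C terminus, and chromatin was precipitated with an antibody against GFP. The design holds 1 group with 2 biological replicates and no second condition, so the comparisons are between the replicates, and between the peaks that passed the authors' reproducibility threshold and the other peaks called from the same reads. The peak lists carry no read counts, so the depth of each library is unknown here. Each peak's signalValue is the authors' own score, and it is used only to describe and rank peaks within a list.

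The thresholded list held 3672 peaks on 2L, 2R, 3L, 3R, 4 and X, and none on Y. All 3672 lay at positions of the pooled list, and they were exactly its 3672 peaks of highest signalValue. Their signalValue ran from 107.0 to 2056.6 with a median of 154.8. The pooled list and each replicate's list held 30000 peaks. After the thresholded peaks and those overlapping them were set aside, 25545 remaining pooled peaks served as the comparison set. All of them scored lower than any thresholded peak, so comparisons with them set stronger peaks against weaker ones.

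The first question was whether both replicates marked the same sites. Among the 3672 strongest peaks of replicate 1, 2710 overlapped one of the 3672 strongest of replicate 2 by at least 1 bp. That is 73.8% (95% exact binomial interval 72.35 to 75.22), against a mean of 1.93% when the replicate 2 peaks were placed at random on the same chromosomes. None of 1000 placements reached the observed share (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). Against peaks drawn from replicate 2's own full list, chance overlap was higher, at 14.51%. Among thresholded peaks, 3669 were matched in both replicate lists, and their signalValues in the replicates had a Spearman's rho of 0.651. The authors' threshold was derived from both replicate lists, so that match follows from the selection and does not answer the question, and the correlation holds only for peaks so selected. The correlation is across peaks, which are not independent replicates.

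**Figure D1:**
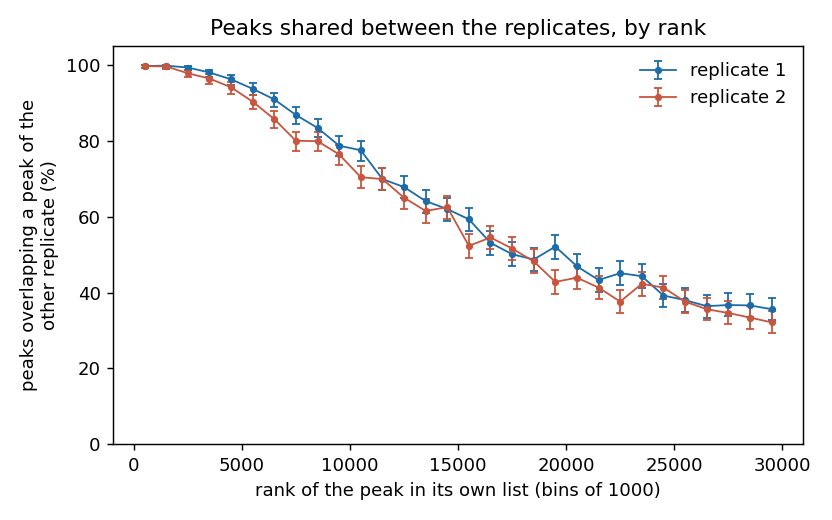
Share of each replicate's peaks (%, vertical axis) that overlap any peak of the other replicate's list, in bins of 1000 peaks by rank (horizontal axis); points are shares and bars 95% exact binomial intervals. The share is 99.7% in the strongest bin of either replicate and falls to 35.6% in the weakest bin of replicate 1 and 32.1% in that of replicate 2.

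The strongest sites lay mostly close to gene starts. Of the 20 thresholded peaks of highest signalValue, 15 had their summit within 500 bp of an annotated transcription start site (TSS), and 17 lay upstream of the nearest one. All 20 ranked within the first 25 peaks of either replicate. The highest peak, with a signalValue of 2056.6, lay on 2L from 6612520 to 6612891 (dm6) in an intron of CG11050, 1019 bp downstream of its TSS. The next, on 3L from 19590447 to 19590776, lay 90 bp upstream of CG14100 with a signalValue of 1884. A peak of 1866 on 2L from 480918 to 481269 lay in an intron of ush, 1420 bp upstream of the nearest TSS, that of cbt, which encodes a zinc-finger transcription factor.

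The peak 175 bp upstream of Gapdh2, a glyceraldehyde-3-phosphate dehydrogenase of glycolysis, reached 1671 (X, 15867809 to 15868132). The peak 26 bp upstream of Ugalt, a UDP-galactose transporter, reached 1662. Peaks upstream of px and CG18549 reached 1649 and 1624. The mitochondrial ribosomal protein gene mRpL41 had a peak of 1621 at 138 bp upstream (2R, 15217599 to 15217908). A peak of 1505 lay between mRpS10 and Art3, at 128 and 129 bp upstream of their TSSs (3R, 15229377 to 15229695).

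The other named peaks had signalValues from 1284 to 1414. They lay nearest to CG13390, to Trl, which encodes the GAGA factor, with CG42507 at a similar distance, and to CG1635, Fkbp14, Pal1 with Pdrg1, Lk6, lncRNA:CR44619, ph-p, CG11309 with CG7632, CenG1A and PNPase. The Trl peak was intronic, 1527 bp downstream of the nearest TSS. The ph-p peak, at a gene of the Polycomb group, lay 484 bp upstream of a TSS within the gene (X, 2137199 to 2137506).

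Thresholded summits were concentrated near TSSs, and few lay in coding sequence farther than 500 bp from a TSS. Within 500 bp of a TSS lay 2175 of 3672 thresholded summits (59.2%) and 7689 of 25545 remaining pooled summits (30.1%), an odds ratio of 3.37 (95% interval 3.14 to 3.62). The median distance to a TSS was 262 bp against 1516 bp. The coding-sequence class leaves out coding sequence within 500 bp of a TSS or in a 5' UTR of any transcript. It held 4 thresholded summits (0.109%) against 1150 remaining ones (4.50%). These 4, named after their values were seen, lay in otp, Pde1c, CG4822 and CG4230, with signalValues of 242, 211, 127 and 111. With replicate 1 alone the class held 6 (0.163%, odds ratio 0.028). With replicate 2 alone it held 8 (0.218%, odds ratio 0.0414). Introns held 29.6% against 42.6%, intergenic sequence 8.88% against 17.9%, 3' UTRs 0.790% against 2.74% and 5' UTRs 0.626% against 1.14%. All 6 of these differences passed Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 7 classes, with adjusted p of 8.86e-251 for the TSS class and 0.00408 for 5' UTRs. Other exons did not (0.790% against 1.06%, adjusted exact p = 0.137), but were called lower with replicate 1 alone (0.708% against 1.09%, adjusted exact p = 0.0377) and against remaining peaks matched on GC content (1.33%, adjusted exact p = 0.0349). Against random positions on the same chromosomes the odds ratio for the TSS class was 9.26, and without the weaker 50% of the remaining peaks it was 2.28. The latter background held 1.79% in coding sequence, for an odds ratio of 0.06 against 0.0231 with all remaining peaks. The 5' UTR difference was no longer called against random positions (adjusted exact p = 0.245) or against remaining peaks matched on GC content (adjusted exact p = 0.487). Each summit has only 1 class and the TSS class is assigned first, so its higher share by itself lowers the shares of the others. A lower share in another class can therefore arise without any depletion there. The higher TSS share alone would leave the proportions between the other classes unchanged. Of the 1497 thresholded summits outside the TSS class, 1086 lay in introns and 4 in coding sequence. Among remaining summits, introns held 10873 and coding sequence 1150. Relative to introns, coding sequence was thus rarer at thresholded summits, which the TSS share alone does not account for. Shares among summits outside the TSS class were not tested. Here and below, tests treat peaks or genes as units, which are not biological replicates.

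**Figure D2:**
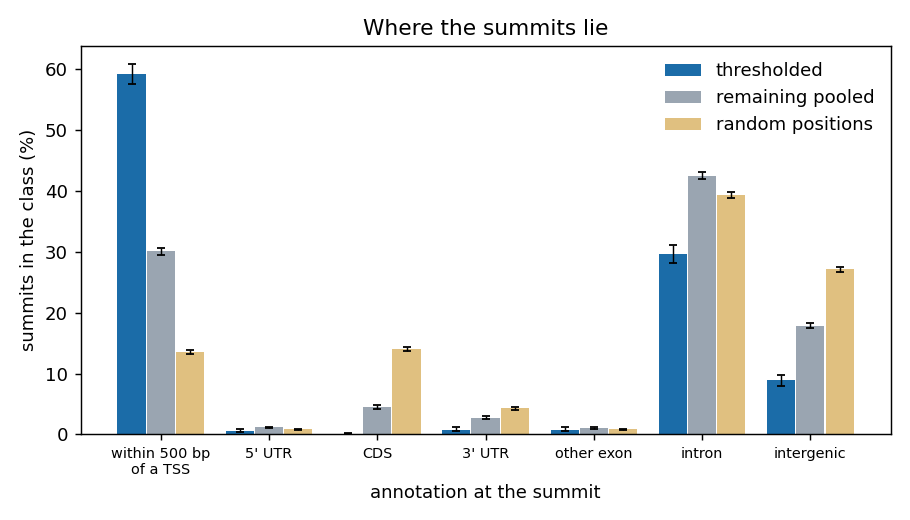
Share of summits (%, vertical axis) in each annotation class (horizontal axis) for thresholded peaks, remaining pooled peaks and random positions, with 95% exact binomial intervals. Thresholded summits lie within 500 bp of a TSS in 59.2% of cases, remaining pooled ones in 30.1%.

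No chromosome arm differed detectably in its share of thresholded and of remaining pooled peaks. The X chromosome held 17.1% against 16.1% (adjusted exact p = 0.377) and 3L held 20.7% against 22.1% (adjusted exact p = 0.314), the arms with the smallest p. Of the 6 arms tested by Fisher's exact test, 0 passed, and 0 had an unadjusted p under 0.05. Against arm length, 2L was called higher (19.2% against 17.1%, adjusted exact p = 0.00352).

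Genes for cytosolic ribosomal proteins, the components of the translation machinery, carried thresholded peaks far more often than other genes. Of 82 such genes with any pooled summit within 1000 bp of a TSS, 70 had a thresholded one (85.4%), against 31.2% of the other genes so marked. The odds ratio was 12.9 (95% interval 6.98 to 23.8, Fisher's exact test, adjusted p = 1.12e-22 over 20 lists). The peak 173 bp upstream of RpL34b had a signalValue of 562, that of RpL7 470 and that of RpS27 441. In both replicates these 3 peaks ranked within the first 265. Mitochondrial ribosomal protein genes did not pass the test as a list, with 24 of 68 (35.3%, adjusted exact p = 0.665), and mRpL41, mRpS10, mRpS23 and mRpL23 carried peaks of 707 to 1621. The mRpS23 peak, 395 bp upstream of that gene, is the one named above at CenG1A, 97 bp upstream. The mitochondrial list passed the test at 5000 bp from a TSS (adjusted exact p = 0.0222) and against all annotated genes (adjusted exact p = 0.0107). For the cytosolic list the odds ratio was 6.80 with the 1836 strongest thresholded peaks and 20.7 against all annotated genes.

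tRNA genes and chemoreceptor genes carried thresholded peaks less often. Of 202 tRNA genes with a pooled summit in range, 22 had a thresholded one (10.9%, odds ratio 0.26, adjusted exact p = 4.05e-11). The strongest of them, of 648, lay 208 bp upstream of tRNA:Tyr-GTA-1-8 and 677 bp upstream of tRNA:Tyr-GTA-1-7. Those 789 bp upstream of tRNA:Val-TAC-1-1 and 181 bp upstream of tRNA:Arg-CCT-1-2 reached 515 and 263. The tRNA share was 23 of 197 with replicate 1 alone (11.7%, odds ratio 0.272). With replicate 2 alone it was 30 of 188 (16.0%, odds ratio 0.416). When only the gene with the nearest TSS was counted, it was 6 of 122 (4.92%, odds ratio 0.139, adjusted exact p = 3.96e-09). Of 32 odorant, gustatory and ionotropic receptor genes, 3 had one (9.38%, odds ratio 0.224, adjusted exact p = 0.0434). These were Or88a, Gr32a and Or9a, with 222, 195 and 111, and the summits lay 700, 680 and 986 bp upstream of a TSS. The chemoreceptor call was lost with the 1836 strongest thresholded peaks (adjusted exact p = 0.336), with the nearest gene alone (adjusted exact p = 0.0518) and among divergent promoters (adjusted exact p = 0.234). It was kept with replicate 1 alone (2 of 34, odds ratio 0.131, adjusted exact p = 0.00235) and with replicate 2 alone (2 of 32, odds ratio 0.147, adjusted exact p = 0.0108).

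Further groups had shares that did not pass the adjustment. Heat shock protein genes had 9 of 15 (60.0%, adjusted exact p = 0.0993), among them Hsp83, Hsp27, Hsc70-5 and Hsp26 with signalValues of 736, 574, 343 and 184, and were called higher with the nearest gene alone (adjusted exact p = 0.0273). Genes for insulator and architectural proteins had 8 of 14 (57.1%, adjusted exact p = 0.135), led by Chro and Cp190, with 1122 and 921, and by Dref and M1BP, with 372 and 240. They were called higher at 5000 bp (adjusted exact p = 0.0108) and against all annotated genes (adjusted exact p = 0.0113). Polycomb and trithorax group genes had 11 of 20 (55%, adjusted exact p = 0.101), with ph-p, E(z), brm and ph-d at 1314, 541, 499 and 451, and were called higher against all annotated genes (adjusted exact p = 0.00291). E(spl) complex genes, targets of Notch signalling, had 5 of 8 (adjusted exact p = 0.238), with E(spl)m7-HLH at 251, E(spl)m3-HLH at 203, E(spl)m2-BFM at 176 and E(spl)malpha-BFM at 124, and were called higher at 5000 bp (10 of 11, adjusted exact p = 0.00522). Small nuclear and nucleolar RNA genes had 61 of 158 (38.6%, adjusted exact p = 0.145), with the strongest peak (776) lying 728 bp upstream of scaRNA:MeU5-C46. With the nearest gene alone they had 7 of 69 and were called lower (adjusted exact p = 0.00625), and at 5000 bp they had 194 of 286 and were called higher (adjusted exact p = 6.35e-16). Within 5000 bp 1 summit can count for several neighbouring genes. The p-values at 5000 bp treat genes that share a summit as separate. Cuticle protein genes had 2 of 23, Cpr73D and Cpr65Ay, with summits 688 and 902 bp downstream of a TSS (8.70%, adjusted exact p = 0.0993). They were called lower with either replicate alone (adjusted exact p = 0.00311 for replicate 1 and 0.0121 for replicate 2). The same call was made at 500 bp, at 5000 bp, against all annotated genes and with the nearest gene alone (adjusted exact p of 0.018 or less).

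The remaining lists did not pass the test either. Hox genes had 0 of 5 (adjusted exact p = 0.608). Segmentation genes had 4 of 13, nkd, ci, ptc and hb, with 389, 176, 112 and 108 (adjusted exact p = 1.0). Neural genes had 2 of 11, elav at 883 and SoxN at 131, mesoderm and muscle genes 3 of 15, tin at 391, sls at 276 and Tm1 at 203, and signalling genes 8 of 21, led by Mad, spi, brk and put with 278 to 135 (adjusted exact p = 0.665 for all 3 lists). Proteasome genes had 11 of 31, led by Rpn3, Rpn13, Rpn9 and Prosbeta1, and germline genes 3 of 8, orb, piwi and gcl (both adjusted exact p = 0.793). Cell cycle genes had 7 of 20, led by CycE, Dp, dpa and Cdk1 (adjusted exact p = 0.853). Histone genes had 3 of 4, His2Av, His3.3B and His4r (adjusted exact p = 0.213), and the His4r peak is the same as the put peak. They were called higher at 5000 bp, with 5 of 5 (adjusted exact p = 0.0341), and lower against all annotated genes, with 3 of 116 (adjusted exact p = 9.36e-07). Only 4 of those 116 have any pooled summit within 1000 bp of a TSS. The lower call thus rests mostly on genes without a called peak, and why they lack one was not tested. Of 2 eye genes, norpA had one (adjusted exact p = 0.665).

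**Figure D3:**
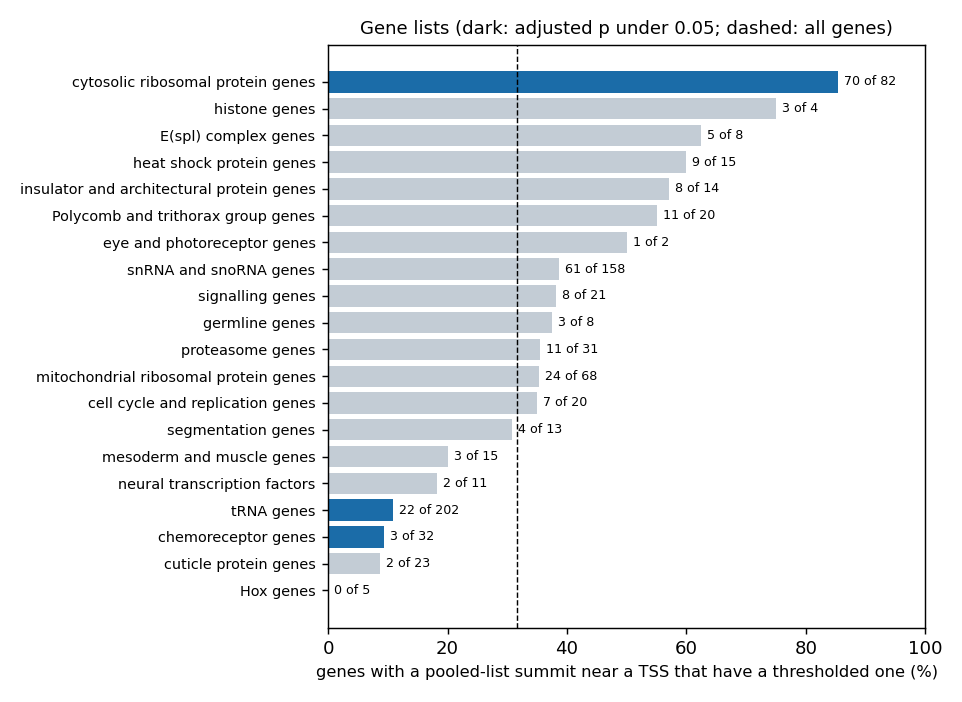
For each gene list (vertical axis), the share (%, horizontal axis) of genes with a pooled summit within 1000 bp of a TSS that also have a thresholded one, with the numbers beside each bar; dark bars passed Fisher's exact test after adjustment, and the dashed line is the share over all genes, 31.6%. Cytosolic ribosomal protein genes stand at 85.4%, tRNA genes at 10.9%.

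The DNA at thresholded summits was rich in A and T. Within 50 bp of the summit the mean GC content was 34.1% (SD 9.96 over 3672 peaks), against 41.3% (SD 10.01) at remaining pooled summits. Sequence 300 to 600 bp away from thresholded summits had 43.3%. All 5 of the 7-mers with the smallest p on the test arms were made of A and T: TTTAAAA, TAAAATA, ATTTTAA, AAATAAA and AATTTTA. TTTAAAA, counted with its reverse complement, was found at 14.1% of thresholded and 6.32% of remaining summits on 3L, 3R and X (odds ratio 2.43, Fisher's exact test, p = 9.88e-34). Of 475 7-mers found on 2L and 2R, 369 held on the test arms, 271 higher and 98 lower, and 247 of the higher ones held at most 1 G or C. With remaining peaks matched on GC content and TSS class, 0 of 8192 7-mers passed (Fisher's exact test, 353 with an unadjusted p under 0.05). A random background of that size left 205 found and 139 held. The GC content matched was that of the window in which the 7-mers were counted. Such matching can itself remove a preference for words of A and T, so it cannot tell that from AT-rich sequence in general.

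**Figure D4:**
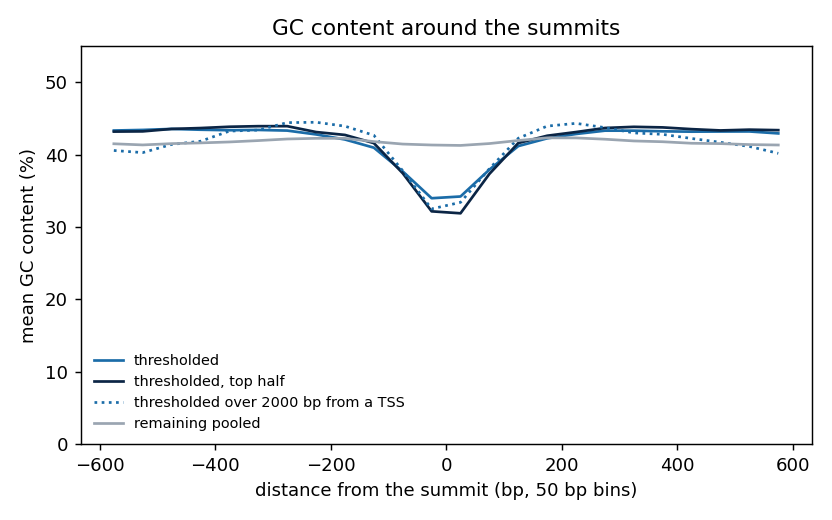
Mean GC content (%, vertical axis) in 50 bp bins by distance from the summit (bp, horizontal axis) for thresholded peaks, the 1836 strongest of them, those over 2000 bp from a TSS, and remaining pooled peaks. Within 50 bp of the summit the means are 34.1%, 32.0%, 32.9% and 41.3%.

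Sequence words of promoter and insulator proteins also differed in frequency. The DNA replication-related element, bound by Dref, was found within 50 bp of 2.02% of thresholded and 0.818% of remaining summits (odds ratio 2.49, adjusted exact p = 1.84e-09). The BEAF-32 word TCGATA stood at 8.01% against 5.08%, Motif 1 at 1.39% against 0.759%, Motif 6 at 1.498% against 0.814%, TATAAA at 23.4% against 13.3%, the homeodomain core TAATTA at 10.7% against 6.53% and the Su(Hw) word at 7.60% against 6.34%. GAGA, CTCF, PHO and Zeste words, both E-boxes and CA repeats were less frequent, such as 11.2% against 15.7% for Zeste and 1.85% against 3.53% for CA repeats. The GAGA difference turned with the window: within 150 bp GAGA words were more frequent at thresholded summits (8.69% against 6.24%, adjusted exact p = 1.43e-07), and they were not called with replicate 1 alone (adjusted exact p = 0.548), within 25 bp (adjusted exact p = 0.254) or within 100 bp (adjusted exact p = 0.458). They were not called against a random background of the matched size either (adjusted exact p = 0.193), nor within 150 bp against flanking windows (adjusted exact p = 0.24). Within 50 bp GAGA words were called lower with the 1836 strongest thresholded peaks (0.817% against 1.98%, adjusted exact p = 0.00039). They were also called lower against flanking windows 300 bp away (1.42% against 3.64%, adjusted exact p = 1.15e-11) and with replicate 2 alone (adjusted exact p = 0.0179). The E-box CAGCTG was not called with either replicate alone (adjusted exact p = 0.107 for replicate 1 and 0.0935 for replicate 2), within 25 bp (adjusted exact p = 0.0664) or within 100 bp (adjusted exact p = 0.905), and was more frequent within 150 bp (15.9% against 14.0%, adjusted exact p = 0.00394). With replicate 2 alone CTCF and PHO words were not called (adjusted exact p = 0.126 and 0.14), and with the 1836 strongest thresholded peaks PHO was not called either (adjusted exact p = 0.586), nor within 25 bp (adjusted exact p = 0.0877) or against flanking windows (adjusted exact p = 0.266). Among the 1836 strongest Motif 1 stood at 0.817% against 0.759% and was not called (odds ratio 1.08 from 1.84, adjusted exact p = 0.78), nor was the E-box CACGTG (adjusted exact p = 0.103). CACGTG was also not called within 100 bp (adjusted exact p = 0.0623) or 150 bp (adjusted exact p = 0.682, and 0.218 against flanks) or against a random background of the matched size (adjusted exact p = 0.429), CA repeats not within 150 bp (adjusted exact p = 0.122) and the Su(Hw) word not within 25 bp (adjusted exact p = 0.0724) or against the random background (adjusted exact p = 0.104). The Zelda word did not differ detectably (0.381% against 0.388%, adjusted exact p = 1.0) and was called lower only within 150 bp against flanking windows (1.03% against 1.88%, adjusted exact p = 0.00113). In all, 14 of 15 words passed Fisher's exact test, 7 higher and 7 lower, and 0 passed against remaining peaks matched on GC content and TSS class (1 with an unadjusted p under 0.05), whereas 11 did against a random background of that size. After matching, the odds ratio of the DNA replication-related element was 1.26 (95% interval 0.892 to 1.78) against 2.49 before, that of Motif 1 was 1.22 against 1.84, that of TCGATA 1.07 against 1.62 and that of TATAAA 1.08 against 1.999. That of Motif 6 was 1.79 (1.15 to 2.78) against 1.85. The other 9 words called before matching had odds ratios of 0.734 to 1.11 after it. Matching on the GC content of the window searched can itself remove differences in words rich or poor in A and T. The matched values therefore do not show that no word is preferred.

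Thresholded peaks near a TSS were slightly stronger than the others. The mean log2 signalValue was 7.52 in 2175 peaks within 500 bp of a TSS and 7.45 in the other 1497, a difference of 0.076 (SE 0.0233, two-sided permutation test, p = 0.00138). With a window of 250 bp the difference was 0.022 and no longer passed (permutation test, p = 0.344), and with replicate 1 alone it was 0.043 (p = 0.0497).

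The CG12299 gene itself carried a thresholded peak at its start. The gene (FBgn0032295) lies on the plus strand of 2L from 10737345 to 10740762, and the peak from 10737209 to 10737592 had its summit 56 bp downstream of the TSS. Its signalValue was 129.5, rank 2560 of the pooled list, and it ranked 4933 in replicate 1 and 1843 in replicate 2. Within 20000 bp of the gene lay 4 thresholded summits. The others lay 81 bp upstream of EMC3 (116.3), 157 bp upstream of mir-9378 in CG17124 (312.9) and 59 bp downstream of the CG17124 TSS (232.2).

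**Figure D5:**
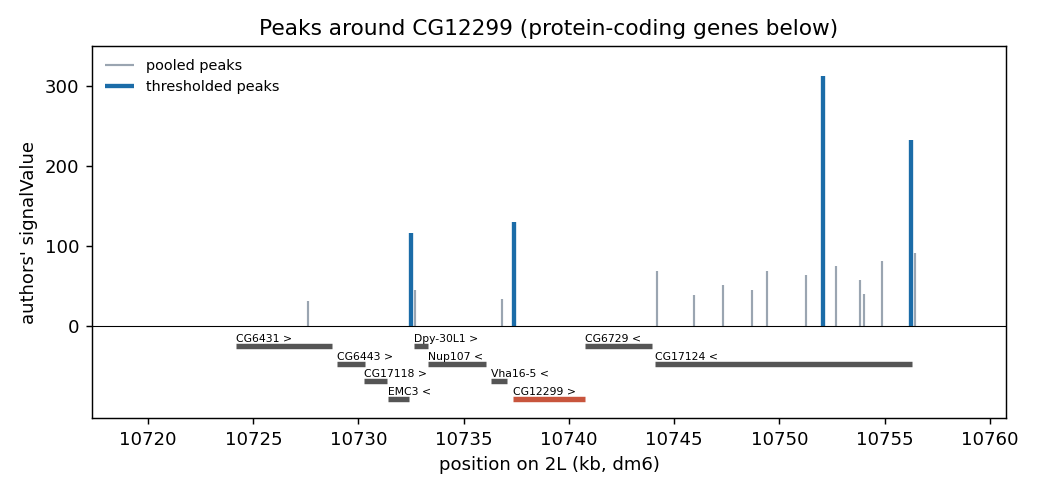
Pooled and thresholded peaks (vertical axis, the authors' signalValue) by position on 2L (horizontal axis, kb, dm6) within 20000 bp of CG12299, with protein-coding genes and their strands below. The peak at the CG12299 start has a signalValue of 129.5, and the strongest, in CG17124, 312.9.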

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

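The random background of the matched size, the backgrounds matched on GC content alone, the windows of 150 bp, the 100 bp window with matching, the divergent promoters and the placements from replicate 2's own list were chosen after seeing the data; the other alternatives were planned. Of the values that answer a comparison, 41 kept their side of the threshold or moved little, 13 moved and 1 no longer passed. Of the values for single classes, arms, lists and words, 329 kept direction and side, 36 lost and 19 gained a call, and 45 turned direction. The cause was not tested except where stated. No paired analysis was possible because there is only 1 group. Without read counts, what depth limits is unknown.

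Spearman's rho was 0.697 in the stronger thresholded peaks. Against arm length 2 arms were called, 2L higher and Y lower. No list holds a peak on Y, so that call follows from the lists and says nothing of binding there. Called gene lists numbered 9 at 5000 bp, 8 against all annotated genes and 5 with the nearest gene. The promoter difference in log2 signalValue was 0.022 at 250 bp. Within 5000 bp of CG12299 lay 2 thresholded summits, a smaller window. Held 7-mers numbered 767 at 100 bp, 559 against flanks at 300 bp, 1334 at 150 bp against flanks at 450 bp and 139 against a random background of the matched size. Matching on GC content and TSS class left 0 words by Fisher's exact test (1 at an unadjusted p under 0.05), and 0 7-mers at 50 bp (353 unadjusted) and 0 at 100 bp (490 unadjusted). The odds ratio of Motif 6 was 1.79 after matching, from 1.85, while those of the DNA replication-related element and the TATA box fell to 1.26 from 2.49 and to 1.08 from 1.999.

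The values that turned direction are log2 odds ratios. With the 1836 strongest thresholded peaks, 3R stood at -0.12 and chromosome 4 at -0.85, mesoderm genes at 0.24, signalling genes at -0.35, proteasome genes at -0.99, cell cycle genes at -0.27 and eye genes at -0.09. With each replicate left out in turn, the ranges were -0.065 to -0.05 for 3R, -0.41 to 0.22 for chromosome 4, -0.17 to 1.21 for signalling genes, -0.074 to 0.33 for germline genes, -1.255 to 1.15 for eye genes and -0.53 to 0.11 for GAGA. Against arm length, 2R stood at -0.005, 3L at 0.023, chromosome 4 at -0.47 and X at -0.001. At 500 bp from a TSS, segmentation genes stood at 0.33, signalling genes at -0.087, snRNA and snoRNA genes at -0.58, cell cycle genes at -0.087 and eye genes at -0.45, and at 5000 bp eye genes at -0.79. Against all annotated genes, segmentation genes stood at 0.035, histone genes at -3.12 and eye genes at -1.69. With the nearest gene alone, proteasome genes stood at -0.32, snRNA and snoRNA genes at -1.71, cell cycle genes at -0.034 and germline genes at -0.87. Among divergent promoters, segmentation and mesoderm genes stood at 0.32, signalling genes at -0.27, mitochondrial ribosomal protein genes at -0.27 and germline genes at -0.096. For words, Zelda stood at 0.38 within 25 bp. GAGA stood at 0.10 within 100 bp, 0.52 within 150 bp and 0.13 there against flanks. The E-box CAGCTG stood at 0.009, 0.21 and 0.22 in the same settings and at 0.054 after matching, where CTCF stood at 0.12.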

Other observations

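No test in this part was among those fixed before the data were examined. Those on cytosolic ribosomal protein genes and on the CG12299 surroundings, and the sequence profiles by distance, were chosen only after their results were seen, and the others before the values they measure were seen.

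Thresholded summits often lay in the short space between genes transcribed away from each other. Of 3672 thresholded summits, 810 (22.1%) lay between a TSS on the minus strand to the left and one on the plus strand to the right at most 1000 bp apart, against 1175 of 25545 remaining pooled summits (4.60%). Among summits within 500 bp of a TSS, 70.8% of thresholded and 53.6% of remaining ones lay upstream of the nearest TSS. A summit between head-to-head TSSs lies upstream of both, so these shares partly repeat the result before. The upstream share without such summits was not tested. The word CACAGTG, singled out after its values were seen, occurred 22.4 times per 1000 thresholded peaks per 50 bp at 50 to 150 bp from the summit, 9.53 times within 50 bp and 6.51 times at 300 to 600 bp. At remaining summits the same zones held 8.46, 8.89 and 5.76. GAGA words at thresholded summits stood at 15.7, 40.8 and 30.9 within 50 bp, at 50 to 150 bp and at 300 to 600 bp. At remaining summits they stood at 20.9, 27.4 and 17.9, also highest at 50 to 150 bp.

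The position between head-to-head genes could follow from a general preference for TSSs. Among peaks within 500 bp of a TSS, 37.2% of thresholded and 15.3% of remaining summits lay between such genes, an odds ratio of 3.29 (95% interval 2.96 to 3.66), so proximity to a TSS alone does not account for it. Gene density and open chromatin at such promoters were not tested and stay open, and the design gives no second group in which a biological explanation could be tested.

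The GC content at thresholded summits was 9.18 percentage points below that 300 to 600 bp away, and 0.30 below at remaining summits. AT-rich promoter sequence may cause such a fall, but in the 768 thresholded peaks over 2000 bp from a TSS it was 8.87 points (95% interval 8.06 to 9.67). Narrowing of peaks by the caller is argued against by a fall of 8.42 points in peaks of the greatest width in the list (7.96 to 8.88), though in narrower peaks it was larger, at 13.9. Neither replicate alone sets it, since the smaller fall in either replicate's strongest peaks was 8.14 points (7.72 to 8.55). A GC bias of the libraries or of the control, and the way the caller places a summit, cannot be examined in peak lists and stay open, and no biological explanation was tested.

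The frequent peaks at cytosolic ribosomal protein genes could come from genes that lie close together and share a peak. Leaving out the 45 genes counted as having another ribosomal protein gene TSS within 5000 bp, the log2 odds ratio was 3.87 (95% interval 2.51 to 5.22) over 38 genes. Among genes with any pooled summit within 500 bp of a TSS it was 3.61 (2.69 to 4.53), a test close to one already seen with a 500 bp window, so it adds little. High transcription of these genes, which can raise ChIP signal at promoters whatever the antibody, was not tested and stays open, and no biological explanation was tested.

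Mitochondrial ribosomal protein genes did not pass their own test, with 24 of 68. Their log2 odds ratio was -0.27 among genes with divergent promoters (95% interval -1.05 to 0.51) and -0.058 over 5 strata of gene density (-0.79 to 0.67). With no excess in that test, these values decide nothing about shared promoters or gene density, and they do not bear on the higher value against all annotated genes, 1.10. Around CG12299, 18 pooled summits within 20000 bp stood at percentile 75.1 of 13968 protein-coding genes, whose median was 13. A number of called summits does not measure copy number, so extra copies of the region from the transgene stay open.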
